A study of Homo sapiens with 8 samples.

How the data were processed

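The series holds 8 samples of total RNA from NHEK cells, 4 controls and 4 exposed to TCDD, each labelled with biotin and hybridised to a whole-transcript sense-target array, per the labels' protocols. RNA was isolated with Stat 60, per the labels. Groups and replicate numbers were taken from the sample titles. The table the authors deposited gives 1 intensity per probe set and array on a linear scale, already summarised over probes. How it was background-corrected, normalized and summarised, with which software and from which genome build, is not given in the sources used here. The array medians were near equal (119 to 128) and the lowest value was 0.81, but the quartiles were not identical between arrays. The table carries no detection calls or background values, and the number of arrays limits the precision.

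The intensities were converted to log2 with no pseudocount, since all were above 0. Probe sets were named from the platform annotation, with symbols checked by gene identifier against a RefSeq gene table (assembly GRCh38.p14), which was used for names only. Of 33252 probe sets, 19460 had 1 gene symbol, 1754 had several and 12038 had none there. A probe set with several symbols was given no name, and 31 single-symbol probe sets had an identifier the RefSeq table did not match. Probe sets of Y-linked genes and XIST, 24 in all, were left out of the gene table. Each of the resulting 18394 genes was represented by its probe set with the highest mean over all 8 arrays. Among 768 genes with several probe sets, 1 (SH3KBP1, named after its values were seen) had probe sets past the threshold in both directions. All 8 values of 990 probe sets equalled those of another probe set, so close gene copies are not always told apart.

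The comparison of TCDD with control was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 on the log2 values, with no block, and adjusted by the Benjamini-Hochberg method over all probe sets or all genes. An adjusted p under 0.05 was called changed, and log2 changes are TCDD minus control. For 24 gene lists, camera with its preset correlation of 0.01 tested whether a list's genes were shifted up or down relative to other genes, adjusted over the lists. A list with many changes in both directions can therefore fail to pass. Tests by camera with an estimated correlation and by fry were run beside it. The lists were AHR target genes, cornified envelope and fused S100 proteins, SPRR, LCE and S100 genes, suprabasal markers, barrier lipid genes, basal and hemidesmosome markers, proliferation, NRF2 and glutathione, reactive oxygen species enzymes, inflammatory genes, EGF receptor and ligands, cholesterol synthesis, proteases, interferon-stimulated genes, Notch, differentiation transcription factors, retinoid genes, endoplasmic reticulum stress, and markers of melanocytes, fibroblasts, leukocytes, and endothelial and Merkel cells.

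Genes were named by a rule fixed, like the lists, the tests and most alternatives, before the data were examined. It took the 12 largest rises and the 12 largest falls among changed genes whose TCDD arrays all lay on the same side of all control arrays, a fixed set of AHR and keratinocyte genes, and from each list up to 4 changed members with the smallest p, or the 2 with the smallest p where fewer than 2 changed. This gave 111 genes. Genes outside the rule are said to have been named after their values were seen.

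The alternatives were quantile normalization, median centring, an intensity trend with a robust prior, array weights, 2 filters on dim probe sets, the replicate number as a block, leaving out each array, no variance moderation, a treat test against a 1.2-fold change, the mean of a gene's probe sets, and an estimated correlation. A fit with TCDD array 4 as the only TCDD array was added after seeing the data. The code was tested on simulated data drawn for the 18394 genes of this comparison, with 200 genes changed in each of 5 runs. It recovered 52.4% of genes changed by 0.5 log2, 91.1% at 1 and 98.8% at 2, with 4.51% of calls false, and a list shifted by 0.3 was called in all 5 runs, with 1 false list call in total. The simulated noise was independent between genes, with no array set apart. These rates therefore test the code and do not give the error rate for lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.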

Results

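RNA levels were measured in NHEK cells, normal human epidermal keratinocytes grown in culture, which form the cornified layers of the epidermis as they differentiate. Of the 8 samples, each labelled as 100% dense, 4 were controls and 4 were exposed to TCDD, a dioxin that binds the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. Each sample was hybridised to 1 whole-transcript array, which gave intensities for 33252 probe sets. Median intensity ran from 122 to 127 over the control arrays and from 119 to 128 over the TCDD arrays. The comparison of TCDD with control addresses what dioxin does to gene expression in dense keratinocytes. The labels give neither dose nor time of exposure, and they do not say whether the 4 samples of a group came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical. The number of arrays, 4 per group, limits the precision of every value.

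TCDD raised CYP1A1 and CYP1B1 most, and the lists of cornified envelope, SPRR and suprabasal genes were higher by camera with its preset correlation, though not with an estimated one (adjusted p = 0.103, 0.103 and 0.211). The lists of interferon-stimulated and of basal keratinocyte genes were lower by the same test, again not with an estimated correlation (adjusted p = 0.198 and 0.211). By limma with Benjamini-Hochberg adjustment, 4418 of 18394 genes changed, 1598 of them upward and 2820 downward. At 2-fold or more, 130 genes rose and 124 fell. The 4 TCDD arrays lay all above or all below the 4 control arrays for 4856 genes, or 26.4%, where chance gives 2.86%. On the level of single probe sets, 4526 of 33252 changed, 1634 upward and 2892 downward.

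TCDD array 4 stood apart. Its mean correlation with the other TCDD arrays was 0.966, below its 0.974 with the controls, and the other TCDD arrays had 0.975 to 0.977 within their group. It lay inside the control range for 372 of the 4418 changed genes (8.42%), against 26 to 46 on each of the other TCDD arrays. Without it, 6663 genes changed, 3050 of them upward, 403 genes changed by 2-fold or more, and 8340 probe sets changed. Without control array 1, 3 or 4 or TCDD array 1, 2 or 3, the probe set count lay between 2464 and 2852.

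**Figure D1:**
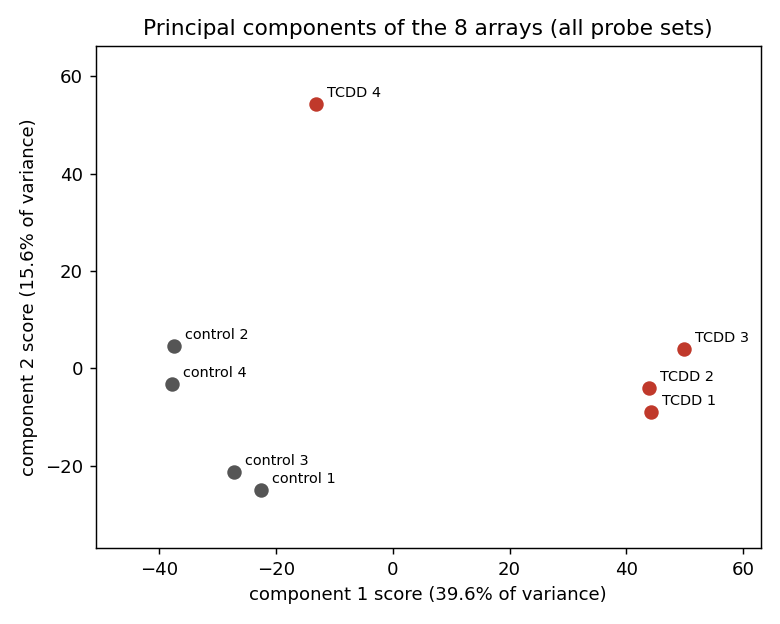
Scores of the 8 arrays on the first principal components of the log2 intensities of all probe sets; the horizontal axis is component 1 (39.6% of variance), the vertical axis component 2 (15.6%), both in score units, and each point is 1 array. Control arrays lie between -37.8 and -22.6 on component 1, TCDD arrays 1 to 3 between 44.0 and 49.8, and TCDD array 4 at -13.1, with the highest component 2 score, 54.3.

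CYP1A1 and CYP1B1, the cytochrome P450 genes best known as AHR targets, showed the largest rises of all genes. CYP1A1 (probe set 7990391) stood at 5.69 ± 0.18 (SD, n = 4) log2 intensity in controls and 12.28 ± 0.14 (SD, n = 4) after TCDD, a 96.1-fold rise (adjusted p = 2.47e-10). CYP1B1 (probe set 8051583) went from 5.96 ± 0.22 to 12.08 ± 0.11 (SD, n = 4), 69.5-fold (adjusted p = 4.80e-10). On TCDD array 4 they reached 12.07 and 12.08. Their control levels lay near the lower quartile of the control arrays (55.4 to 60.1 in intensity), and with no background values in the table these folds are not corrected for background. Of 9 measured AHR target genes, 5 rose and 0 fell, also 5 when adjusted over the list alone. The other risers moved far less. NQO1, a quinone reductase, rose by 0.46 ± 0.08 log2 (SE, adjusted p = 0.00229) and the amino acid transporter SLC7A5 by 0.51 ± 0.09 (SE, adjusted p = 0.00258). TIPARP, another AHR target, differed by 0.14 (adjusted p = 0.185), and ARNT, the dimerisation partner of AHR, by 0.08 (adjusted p = 0.413). AHR itself fell by 0.34 (adjusted p = 0.0289), a call lost without control array 1, 3 or 4 or TCDD array 1 or 2 (adjusted p = 0.0631 to 0.0908) and without variance moderation (adjusted p = 0.0588). The list's median change was 0.46 (camera adjusted p = 2.57e-05; adjusted p = 0.103 with an estimated correlation). AHRR, the UGT1A genes and TP63 have no probe set of their own in the annotation used and were not analysed here.

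Among changed genes whose TCDD arrays all lay on the same side of all control arrays, the next largest rise was that of MMP1, interstitial collagenase (9.26-fold, 3.21 ± 0.11 log2, SE). LCE3A, a late cornified envelope gene, rose 6.75-fold, and GPAT3, an acyltransferase of glycerolipid synthesis, 6.43-fold. ACP7 rose 5.77-fold, the cytokine gene IL1B 5.70-fold, the tight junction gene CLDN17 5.01-fold, the protease inhibitor gene SPINK7 4.83-fold, IL36G 4.62-fold and S100A7 4.28-fold. Their adjusted p-values ran from 3.61e-08 for ACP7 to 3.79e-05 for S100A7. The small nucleolar RNA SNORD15B rose 4.24-fold on average (adjusted p = 0.00631), with a log2 difference from the control mean of 0.50 on TCDD array 4, and its call was lost without variance moderation (adjusted p = 0.0515).

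Of the 12 largest falls among genes with the same separation of arrays, 4 were in genes known to be interferon-inducible: IFI44L (3.85-fold), IFI44 (3.34-fold), TRIM22 (3.22-fold) and IFIT1 (2.94-fold). PPP1R3C, a glycogen-targeting phosphatase subunit, fell 4.40-fold, and the snoRNA SNORD61 fell 4.56-fold. The metal-binding and antioxidant genes MT1X (3.57-fold), SELENOP (3.51-fold) and GSR (3.09-fold), together with ARL6IP5 (3.26-fold), GTF3C6 (3.04-fold) and GLUL (2.86-fold), made up the rest. HPGDS (-3.01, adjusted p = 0.0465) and TMEM39B (-2.15, adjusted p = 0.0117), named after their values were seen, fell further than PPP1R3C on average but lay inside the control range on TCDD array 4. On TCDD array 4, GTF3C6 lay 0.26 log2 below its control mean of 9.25 ± 0.22 (SD, n = 4). Its call was lost without variance moderation (adjusted p = 0.0619), and the adjusted p of the other genes in this group of falls was at most 0.000877, that of SNORD61.

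**Figure D2:**
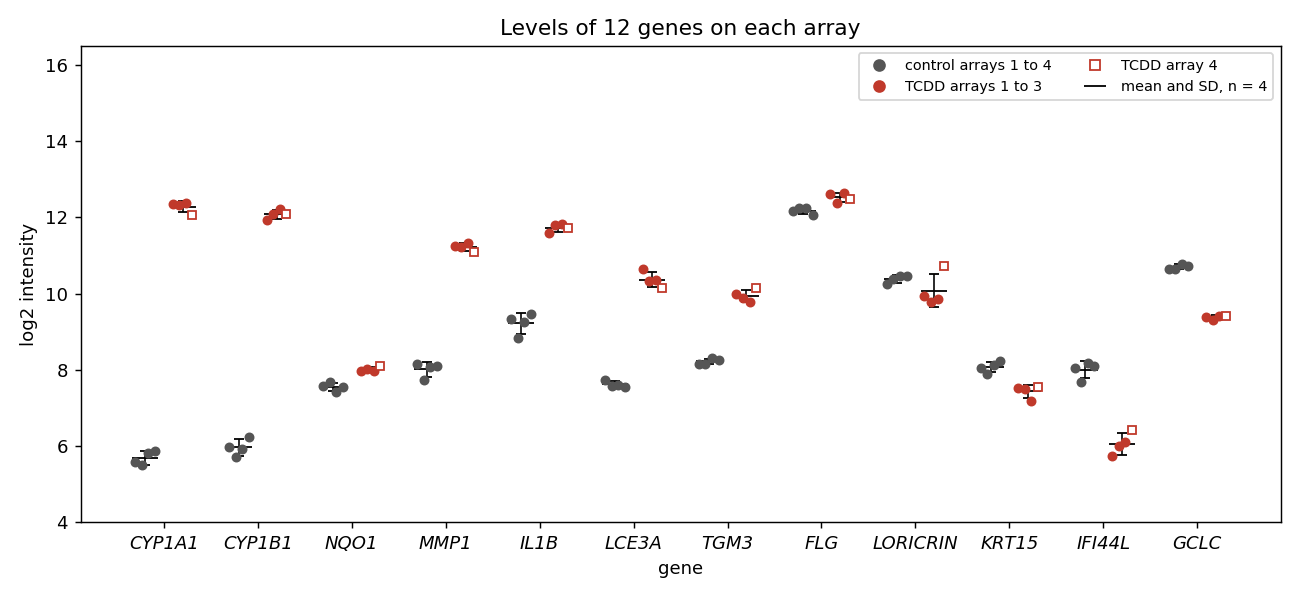
Log2 intensity (vertical axis) of 12 genes (horizontal axis) on each control array (grey) and TCDD array (red, with TCDD array 4 as an open square); horizontal ticks with bars give the mean and SD of 4 arrays. CYP1A1 and CYP1B1 lie near 12 on every TCDD array, including array 4 (12.07 and 12.08), against 5.69 and 5.96 in the controls, while LORICRIN on TCDD array 4 (10.72) lies above its controls.

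Genes that encode or cross-link proteins of the cornified envelope rose in several groups but not uniformly. Of 17 measured cornified envelope and fused S100 genes, 10 rose and 0 fell (11 rose adjusted over the list alone), among them CST6 (1.34), CNFN (1.19), FLG2 (0.76) and PPL (0.67). Filaggrin, FLG, rose by 0.36 (adjusted p = 0.0126) and TGM1, a cross-linking transglutaminase, by 0.48 (adjusted p = 0.00475). Involucrin, IVL, differed by 0.32 (adjusted p = 0.0763; adjusted p = 0.0480 with an intensity trend and robust prior). LORICRIN differed by -0.31 (adjusted p = 0.249), and without TCDD array 4 by -0.53 (adjusted p = 0.000893). The list's median was 0.37 (camera adjusted p = 6.38e-07; adjusted p = 0.103 with an estimated correlation). Of 10 small proline-rich SPRR genes, 8 rose and 0 fell, likewise 8 over the list alone, with SPRR4 (1.73), SPRR2A (1.69) and SPRR2B (1.35) in front. Their median was 0.57 (camera adjusted p = 6.38e-07; adjusted p = 0.103 with an estimated correlation).

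LCE genes split. LCE3A (2.75), LCE3E (1.75) and LCE3D (1.12) rose, while LCE1A and LCE1C fell, and 13 of 18 did not pass. LCE1A was named after its values were seen. LCE1C fell by 0.40 (adjusted p = 0.0160; adjusted p = 0.0506 without TCDD array 2), and the fall of LCE1A was lost under quantile normalization and median centring and without control array 1 or 2 or TCDD array 1 or 3. Without TCDD array 4, 4 LCE genes rose and 5 fell, and without control array 1 or 2 or TCDD array 1, 2 or 3 only 1 fell. Adjusted over the list alone, 4 rose and 3 fell. The median was 0.06, and ran from 0.00 (without TCDD array 4) to 0.08 (without control array 1) with 1 array left out. The list did not pass its test (camera adjusted p = 0.119), but did without control array 2 (adjusted p = 0.0365) and without TCDD array 3 (adjusted p = 0.0391). With TCDD array 4 as the only TCDD array its median was 0.21. Of the 16 S100 genes, 5 rose and 2 fell (6 and 2 over the list alone; 1 fell when control array 1, 2, 3 or 4 or TCDD array 2 or 3 was left out), with S100A7 (2.10), S100A9 (1.26), S100A12 (0.81) and S100A8 (0.50), which encode antimicrobial and inflammatory calcium-binding proteins, among the risers. Their median was 0.19 (camera adjusted p = 0.00443; adjusted p = 0.211 with an estimated correlation), but 0.00 on TCDD array 4 and 0.34 with probe sets below the median level left out.

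Suprabasal markers rose as well, with 16 of 36 up and 2 down (18 and 3 adjusted over the list alone; 1 down without control array 3 and 4 without TCDD array 4). The transglutaminase genes TGM3 (1.72) and TGM5 (1.15), the protease gene KLK6 (0.93) and the corneodesmosome gene CDSN (0.85) had the smallest p-values among the risers, while the keratin KRT1 fell by 0.28 (adjusted p = 0.0138; adjusted p = 0.0515 without control array 3). KRT10 differed by -0.19 (adjusted p = 0.140; adjusted p = 0.0205 without TCDD array 4). The median of the list was 0.26 (camera adjusted p = 1.21e-06; adjusted p = 0.211 with an estimated correlation). Epidermal barrier lipid genes moved both ways, 16 of 36 up and 5 down (16 and 6 over the list alone). The glucosylceramide synthase UGCG (0.92), the lipid transporter ABCA12 (0.78) and the lipoxygenase ALOX12B (0.76) rose, and the ceramide synthase CERS6 fell by 1.04. Their median was 0.26 (camera adjusted p = 0.000759; adjusted p = 0.240 with an estimated correlation).

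Transcription factors of keratinocyte differentiation rose in 18 of 34 cases and fell in 1 (19 and 1 adjusted over the list alone), the faller being AHR; without TCDD array 4, 2 fell. OVOL1 (1.24), PRDM1 (1.21), PPARD (1.10) and DLX3 (0.97) had the smallest p-values among them. Their median was 0.41 (camera adjusted p = 1.49e-07; adjusted p = 0.211 with an estimated correlation), and 0.20 on TCDD array 4.

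Basal keratinocyte and hemidesmosome genes, which anchor the proliferating layer, went the other way. Of 18, 0 rose and 10 fell (1 and 10 adjusted over the list alone; 1 rose without TCDD array 4), including CAV1 (-0.94), the plakin DST (-0.68), the basal keratin KRT15 (-0.64) and the integrin ITGA2 (-0.44). The median was -0.29 (camera adjusted p = 0.000263; adjusted p = 0.211 with an estimated correlation). KRT5 fell by 0.22 (adjusted p = 0.0496), a call that ended under median centring (adjusted p = 0.0905) and without each array in turn other than TCDD array 4 (adjusted p = 0.0788 to 0.126). KRT14 differed by -0.09 (adjusted p = 0.477). Of 39 proliferation genes, 1 rose and 6 fell, also 1 and 6 over the list alone (0 rose without control array 2 or 4 or TCDD array 1 or 2, and 2 without TCDD array 4), with the replication clamp PCNA (-0.90), the ribonucleotide reductase subunit RRM2 (-0.68), TOP2A (-0.36) and MCM4 (-0.31) among the fallers. As a list they did not pass the test (median -0.08, camera adjusted p = 0.113), but did without TCDD array 2 (adjusted p = 0.0392) and under quantile normalization (adjusted p = 0.0240). The list median was -0.04 without TCDD array 4, -0.05 without control array 1 and -0.24 with TCDD array 4 as the only TCDD array.

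Cytokine, growth factor and protease genes rose more often than they fell. Of 33 inflammatory cytokine and chemokine genes, 9 rose and 2 fell, also over the list alone (1 fell without control array 1, 3 or 4 or TCDD array 2). IL1B (2.51), IL36G (2.21) and the receptor antagonist gene IL1RN (0.93) rose, and the chemokine gene CXCL14 fell by 1.26. Their median was 0.17 (camera adjusted p = 0.000893; adjusted p = 0.211 with an estimated correlation), but -0.03 on TCDD array 4 and 0.42 with probe sets below the median level left out. Of 16 EGF receptor and ligand genes, 7 rose and 1 fell (8 and 1 over the list alone). The ligands EREG (1.01) and TGFA (0.77), the receptor EGFR (0.44, adjusted p = 0.00509) and the feedback gene SPRY4 (0.78) rose, and LRIG3 fell by 0.88. The median was 0.29 (camera adjusted p = 0.000511; adjusted p = 0.211 with an estimated correlation). Of 26 protease and plasminogen genes, 11 rose and 3 fell (13 and 3 over the list alone; 7 rose without TCDD array 1, and 1 fell without control array 1, 3 or 4), with the matrix metalloproteinases MMP1 (3.21), MMP10 (1.27) and MMP3 (1.16) and the inhibitor TIMP2 (0.66) rising. Their median was 0.24 (camera adjusted p = 0.000511; adjusted p = 0.193 with an estimated correlation).

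Interferon-stimulated genes were lower as a list. Of 29 measured, 16 fell, 1 rose and 12 did not pass, also over the list alone, with a median change of -0.46 (camera adjusted p = 1.49e-07; adjusted p = 0.198 with an estimated correlation). The median on the single TCDD arrays ran from -0.55 to -0.46. The controls also varied in this list, with a median from the other controls of -0.22 on control array 2 and 0.19 on control array 3. IFI44L (-1.95), IFI44 (-1.74) and the RNA sensor IFIH1 (-1.32) had the smallest p-values among the fallers. OASL, an OAS family member known to be inducible without interferon, rose by 1.39.

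Genes of redox defence moved in both directions. Of 31 NRF2 and glutathione genes, 3 rose and 9 fell (3 and 10 over the list alone; 5 rose without TCDD array 4), and the list did not pass its test (median -0.06, camera adjusted p = 0.178). HMOX1, haem oxygenase 1, rose 2.80-fold, and ME1 rose by 0.71. GCLC, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, fell 2.50-fold, and GSR, glutathione reductase, fell 3.09-fold. Of 29 enzymes that produce or remove reactive oxygen species, 5 rose and 7 fell (6 and 8 over the list alone). Spermine oxidase, SMOX (1.18), and xanthine dehydrogenase, XDH (0.74), rose, while superoxide dismutase 1, SOD1, fell by 1.16 and MT1X by 1.84 (list median -0.02, camera adjusted p = 0.769).

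Single genes changed in 4 further lists that did not pass the camera test. Among 23 retinoid genes, 4 rose and 3 fell, the same counts as over the list alone (1 fell without control array 1, 3 or 4), with the retinoic acid synthesising ALDH1A3 (2.04, 4.12-fold), RARG (0.61) and RARRES1 (0.51) up and DHRS3 down by 0.44 (camera adjusted p = 0.195). Among 18 cholesterol synthesis genes, 1 rose and 4 fell, also over the list alone (3 rose without TCDD array 4), the fallers being STARD4 (-1.02), SC5D (-0.71), LSS (-0.65) and CYP51A1 (-0.43; list camera adjusted p = 0.470). Of 25 endoplasmic reticulum stress genes, 4 rose and 2 fell (5 and 2 over the list alone; 8 rose without TCDD array 4), with EDEM1 (0.55) and ATF6 (0.38) up and DDIT3 (-0.71) and PDIA6 (-0.58) down (camera adjusted p = 0.147). Of 20 Notch pathway genes, MAML3 rose (0.61) and JAG1 fell (-0.39), also over the list alone, but 2 rose without TCDD array 2, 2 fell without control array 2, and 4 rose and 2 fell without TCDD array 4 (camera adjusted p = 0.878, with a list median of -0.03 and a mean of 0.02).

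Among markers of cell types other than keratinocytes that such a culture could hold, 3 genes changed, COL1A1, DCN and TYROBP. Without TCDD array 4, 2 melanocyte markers rose, 2 fibroblast markers rose and 1 fell, 3 leukocyte markers rose and 2 fell, and 1 endothelial or Merkel cell marker rose. Without control array 4, 2 fibroblast markers rose. Of 14 melanocyte markers, 0 changed in limma, with 2 at an unadjusted p under 0.05. EDNRB differed by 0.28 (adjusted p = 0.122) and MITF by 0.20 (adjusted p = 0.127; adjusted p = 0.0422 without TCDD array 4), and the camera adjusted p of the list was 0.195. Of 15 endothelial and Merkel cell markers, 0 changed in limma, with 1 at an unadjusted p under 0.05. PIEZO2 differed by 0.20 (adjusted p = 0.123; adjusted p = 0.0399 without TCDD array 4) and VWF by 0.12 (adjusted p = 0.495), with a list camera adjusted p of 0.341. Among 16 fibroblast markers, COL1A1 rose by 0.89 and DCN fell by 0.96 (list camera adjusted p = 0.178). Among 14 leukocyte markers, TYROBP fell by 0.83 (adjusted p = 0.0111), with a value of 10.20 on TCDD array 4 against 10.33 ± 0.07 (SD, n = 4) in controls, and the call ended without variance moderation (adjusted p = 0.0624). FCER1G differed by -0.41 (adjusted p = 0.129; adjusted p = 0.00188 without TCDD array 4), and the camera adjusted p of that list was 0.627, with a median of 0.10 and a mean just below 0. For each of these 4 lists the counts adjusted over the list alone equalled those over all genes.

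**Figure D3:**
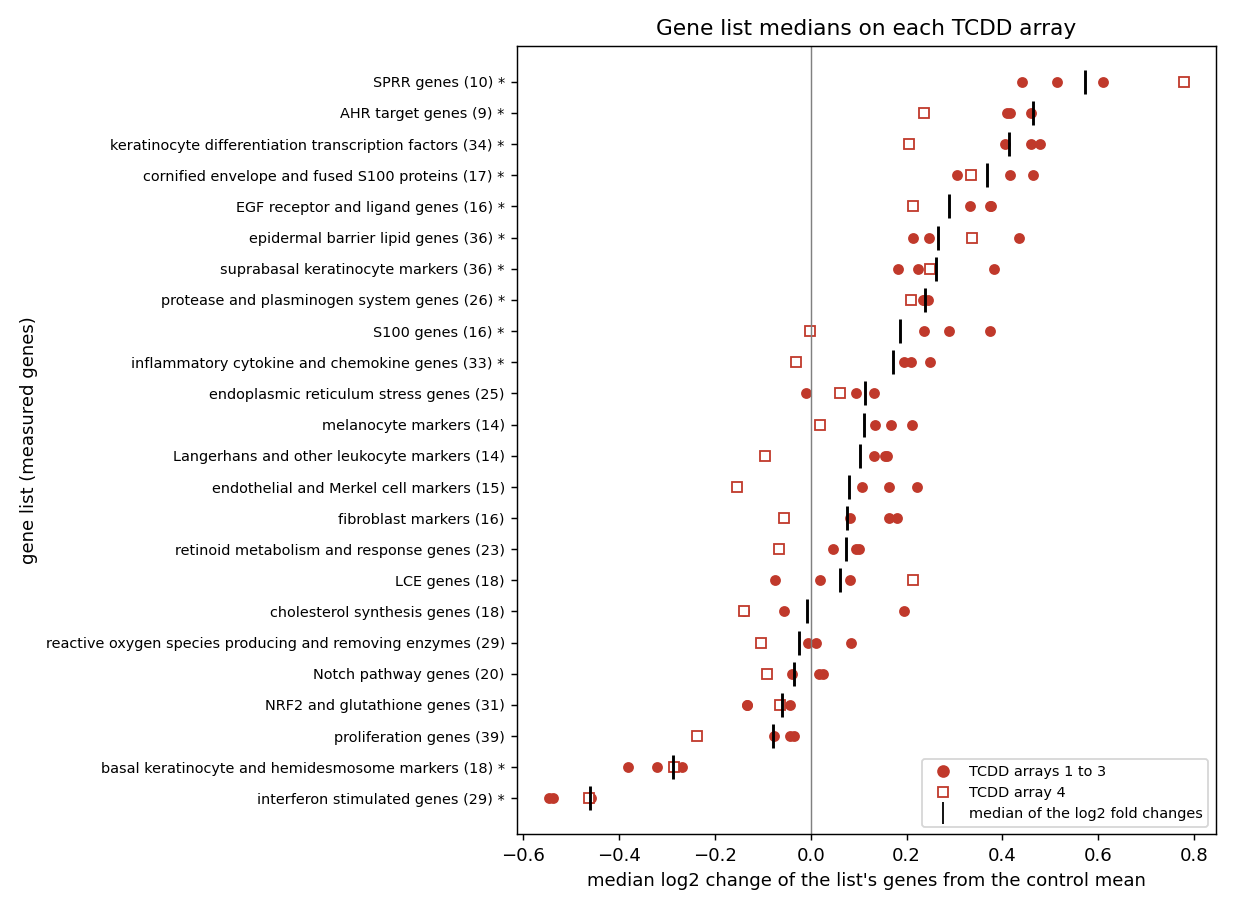
Median log2 change from the control mean (horizontal axis) of the genes of each list (vertical axis, with the number of measured genes) on each TCDD array, with array 4 as an open square and the median of the fitted log2 fold changes as a black tick; an asterisk marks lists with a camera adjusted p under 0.05. Interferon-stimulated genes lie between -0.55 and -0.46 on the 4 arrays, and S100 genes and inflammatory genes lie at 0.00 and -0.03 on TCDD array 4.

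In all, camera called 12 of the 24 lists, 10 upward and 2 downward, with its preset correlation. With an estimated correlation it called 0, and 5 lists had an unadjusted p under 0.05. fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes, called 16. These were the 12 lists that camera called and 4 others. The others were NRF2 and glutathione (fry adjusted p = 0.000745), LCE (0.00369), retinoid (0.00683) and endoplasmic reticulum stress genes (0.0227). Of the 35 ways to split the 8 arrays into groups of 4, 9 called 12 lists or more, the real split included. The 8 others all exchange 1 array between the groups and so keep part of the contrast. Splits that exchange 2 arrays called at most 4. The number of lists called is thus not larger than some splits that exchange 1 array gave.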

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

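The tests of TCDD array 4 and the scaling and single-array tests of the interferon-stimulated genes were chosen only after the results were seen, while the other tests here were written down first. Of the 35 ways to split the 8 arrays into 4 and 4, only 1, the real split, called as many as 4526 probe sets, 4418 genes or 254 genes at 2-fold or more. The highest of the other splits called 2 probe sets, 0 genes and 0 genes at 2-fold. Every other split mixes TCDD and control arrays, which widens the spread within its groups, so few calls there were likely in advance. The counts were thus largest for the labelled groups, but these splits alone cannot exclude chance or a batch that coincides with the groups. For the number of gene lists called, 12 in the real split, chance cannot be excluded either, since 9 of 35 splits called as many and the highest of the others called 13. The 8 other splits that did were among the 16 that exchange 1 array between the groups, and none of the 18 that exchange 2 arrays called more than 4. For 10 of the 12 called lists the median change was largest in the real split, the exceptions being S100 and inflammatory genes, for each of which 3 of 35 splits gave a median as far from 0. This per-list count was added after the list count was seen. The 12 lists were called on the real split, and mixed groups shrink a median, so this outcome was likely in advance. The median of the endoplasmic reticulum stress list (0.11), which was not called, was also largest only in the real split.

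Among 222 groups of 4 values for the named genes, 17 had an extreme array whose gap to the nearest other, as a share of the group's range, exceeded the 95% critical value of Dixon's test, where chance gives about 1 in 20 groups, or 11.1. TCDD array 4 was the extreme array in 7. It was low for IL36G (9.14, mean of the others 9.70), S100A7 (11.05 against 11.78) and SPRR4 (11.06 against 11.68), and high for EDEM1 (9.46 against 9.33), KRT10 (13.53 against 13.28), LORICRIN (10.72 against 9.86) and GTF3C6 (9.0 against 7.20). Control array 2 was low for OVOL1 (8.67), S100A12 (8.67), ME1 (10.58) and IVL (11.72). TCDD array 1 was high for TIMP2 (10.89), TGM1 (12.07) and IVL (12.51), and TCDD array 3 was low for KRT15 (7.19). PIEZO2 was high on control array 1 (6.29) and SNORD61 on control array 4 (6.93). Of 48 groups of list medians, 4 met the same criterion. Control array 2 lay at -0.12 from the control mean for AHR targets, at -0.06 for NRF2 and glutathione genes and at -0.11 for fibroblast markers, and TCDD array 4 lay at -0.10 for leukocyte markers. By the same criterion the mean correlation of TCDD array 4 with its group, 0.966 against a mean of 0.976 for the others, was extreme.

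TCDD array 4 lay inside the control range for 41 genes on which the other 3 TCDD arrays were all at least 2-fold from the control mean, and the same criterion gave 0 genes for each of TCDD arrays 1, 2 and 3. For those arrays fewer genes could qualify (94 to 106, against 255), since TCDD array 4 had to change at least 2-fold too. A control array labelled as TCDD is argued against by CYP1A1 and CYP1B1, the lower of which stood 5.84 log2 above the highest control array. The share of control RNA that single genes allow does not decide on dilution with control RNA as the whole cause. CYP1A1 allows 17.8% of control RNA (22.3% with 2 SD of the other TCDD arrays added) and CYP1B1 0.459%. The 255 genes that the other 3 TCDD arrays all change at least 2-fold, chosen without array 4, give a median of 37.5% (95% limits 30.1 to 45.2, genes taken as independent). That choice takes genes extreme on those 3 arrays, which can raise the share. The 254 genes called at 2-fold or more with all arrays give a median of 19.5% (quartiles 4.07 to 49.9), close to the CYP1A1 value. Of the 255, 16 lie beyond the controls on the opposite side, against at most 1 of the 94 to 106 genes chosen likewise for each other TCDD array. These 16 argue against dilution as the whole cause. Dilution as part of the cause stays open, as no value here excludes a smaller share, and a difference in RNA handling or array processing cannot be told apart from a difference between cultures, with 0% of 341 olfactory receptor genes showing the pattern (exact 95% upper limit 1.08%) against 0.227% of other genes. Small nuclear and nucleolar RNA genes made up 12 of the 41 (6.00% of 200), which may point to RNA handling, but that class was noticed first and tested on the same data, and no biological explanation was tested because the labels name nothing that sets this sample apart. The median change of this class was 0.26, 0.20 and 0.43 on TCDD arrays 1, 2 and 3 and -0.04 on array 4. On each control array against the other controls it lay between -0.06 and 0.05. These values do not tell whether a handling difference would lie with TCDD array 4 or with TCDD arrays 1 to 3, which was not tested.

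The interferon-stimulated genes were lower after TCDD, with a median of -0.46, a call lost with the correlation estimated between these genes (0.186, adjusted p = 0.198). Array scaling is argued against, since the median was still -0.40 at its highest under quantile normalization and median centring, and so is the difference of TCDD array 4, on which the median was -0.46. A drift of dim probe sets is argued against by 10000 random lists matched on mean level, whose lowest median was -0.16. The p from this sampling of genes was 1e-04, the smallest it can give, with genes taken as independent and no arrays exchanged. Only 1 of 35 splits, the real one, gave a median as far from 0, and the highest of the others was 0.37. Every other split mixes TCDD and control arrays, which pulls the median toward 0, so the splits cannot exclude chance here. A lowering of interferon-stimulated genes by TCDD is therefore a candidate explanation, as a hypothesis found and tested on the same data, with any difference in culture or array batch between the groups left untested because the labels give no batch.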

How the results depend on the processing

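The fit with TCDD array 4 as the only TCDD array was chosen after seeing the data. The number of changed probe sets moved most, from 4526 to 8635 with array weights, 891 in the treat test against a 1.2-fold change and 23 with TCDD array 4 alone, and from 2464 (without control array 3) to 8340 (without TCDD array 4) when arrays were left out. Changed genes went from 4418 to 6743 with array weights and 1434 with TCDD array 4 alone, and from 3227 to 6663 over the left-out arrays. Genes higher in TCDD went from 1598 to 2892 with array weights, 503 with TCDD array 4 alone and 1120 to 3050 over the left-out arrays, genes lower from 2820 to 931 with TCDD array 4 alone, and genes changed at least 2-fold from 254 to between 208 and 403 over the left-out arrays. A stricter null lowers the count of the treat test by construction. Fewer arrays lower the power, yet leaving out TCDD array 4 raised the counts, so the number of arrays alone does not set them. The cause of the other changes in count was not tested beyond the weight or absence of TCDD array 4. With TCDD array 4 alone, 4365 of the 4418 changed genes had the same direction, and its lone value was assumed to vary like the controls. All 4418 had the same direction under both scalings and with each array left out. These genes were called with every array in the fit, so agreement of direction on part of the arrays is largely set by that selection. The share of calls that were upward was 36.2%, 43.3% under quantile normalization and 40.8% under median centring.

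With an estimated correlation 0 of 12 list calls remained, at the same medians: AHR targets 0.46, cornified envelope 0.37, SPRR 0.57, S100 0.19, suprabasal 0.26, barrier lipid 0.26, inflammatory 0.17, EGF receptor 0.29, protease 0.24, differentiation transcription factors 0.41, basal -0.29 and interferon -0.46. Under the other alternatives each of these 12 stayed past the threshold wherever it had a value, and the left-out arrays gave 12 or 13 lists. With TCDD array 4 alone 15 lists passed, with LCE (0.21), proliferation (-0.24) and endoplasmic reticulum stress genes (0.06) added, and proliferation (-0.12) also passed under quantile normalization. With the filter at the median level, 3 lists and 14 of 111 named genes were not measured. Of the named genes, 25 lost their call with TCDD array 4 alone, 4 without variance moderation, 1 under median centring and 0 under quantile normalization; none of the called ones reversed. The table gives no signal over background, so values of dim genes carry no stated floor.

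The replicate numbers were not taken as pairs. Deviations of control and TCDD arrays of the same number correlated at 0.125, -0.047, 0.060 and 0.158, and 2 of 4 control and 3 of 4 TCDD arrays correlated best with their own number. With the replicate number as a block, 3025 probe sets and 4565 genes changed, and the paired fit ended the call of KRT5 among the named genes and of 0 lists.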

Other observations

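The tests of gene families in this part were chosen only after the data were seen. A scan of 246 groups of genes with a shared symbol stem and at least 10 members gave 22 with a camera adjusted p under 0.05, 10 upward and 12 downward, and 0 with an estimated correlation (lowest adjusted p = 0.784, with 12 at an unadjusted p under 0.05). The upward ones included the OR stem of olfactory receptor genes (camera adjusted p = 0.0155). Of its 361 genes, 22 rose and 6 fell, with a median of 0.11, and -0.04 on TCDD array 4. A small shift shared by many genes can thus pass this scan, and whether it contributes to other families was not tested. Metallothioneins, which bind zinc and copper, were lower as a family. Of 15 genes and pseudogenes, 9 fell and 0 rose, with MT1X (-1.84), MT1E (-1.02) and MT2A (-0.64) among them (family median -0.43, camera adjusted p = 0.000204; adjusted p = 0.784 with an estimated correlation). These copies are close in sequence, so 1 transcript can hybridise to several probe sets. Of 13 PARP genes, which encode ADP-ribosyltransferases, 8 fell and 0 rose (median -0.49, camera adjusted p = 0.0128; adjusted p = 0.784 with an estimated correlation). PARP9 (-1.46), PARP14 (-0.87) and PARP12 (-0.76), all known to be interferon-inducible, were among them, as was PARP1 (-0.91), a DNA repair enzyme.

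The SRSF and UTP families were also lower. Of 12 SRSF genes, which encode splicing factors, 6 fell, SRSF7 (-0.89) and SRSF10 (-0.79) most (camera adjusted p = 0.00762; adjusted p = 0.784 with an estimated correlation), 0 rose as deposited and 1 rose under either scaling alternative. Of 10 UTP genes, whose products process pre-ribosomal RNA, 7 fell and 0 rose, with UTP4 (-0.84) and UTP15 (-0.78) among them (camera adjusted p = 0.00200; adjusted p = 0.873 with an estimated correlation). In the other direction, 4 of 14 TMPRSS serine protease genes rose, including TMPRSS13 (0.85) and TMPRSS11D (0.79; camera adjusted p = 0.00532; adjusted p = 0.784 with an estimated correlation), and 5 of 12 SERPINB genes rose, with SERPINB9 (0.52), SERPINB11 (0.49) and SERPINB8 (0.48) in front (camera adjusted p = 0.0135; adjusted p = 0.0530 without TCDD array 4, and 0.873 with an estimated correlation). The family medians had the same sign under quantile normalization and median centring. Probe sets without a gene symbol in the annotation, 12038 in all, included 390 that rose and 477 that fell, of which 146 changed by 2-fold or more.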
